A study of Mus musculus with 20 samples.

How the data were processed

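RNA was measured in 20 soleus muscle samples of C57BL/6J mice, 10 control and 10 exposed. Per the labels' protocols, tissue was homogenised in TriZol, RNA was purified on columns, and libraries depleted of ribosomal RNA were made from 90 ng of total RNA and sequenced as paired-end reads on a NovaSeq X Plus. The authors deposited a single table of raw read counts per Ensembl gene, with no normalization, and per the submitters' processing notes the work used MultiQC 1.15, Subread, featureCounts 1.5.1, edgeR and the genome build GRCm39. The roles of these tools, the strand setting, the annotation release and the treatment of reads that match several genes are not given in the sources used here. Library codes in the table header were matched to the sample descriptions, and groups were taken from the labels. No column was left out.

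The annotation at hand was GENCODE M21 on the older build GRCm38. It was used for gene names and gene classes and, within that build, for which transcript models lie inside introns, and no coordinates are printed. Names were matched by Ensembl identifier for 51948 of 56941 rows, which held 97.6% of counts. The largest row with no name held 1.82% of counts and was kept. lncRNAs, pseudogenes and protein-coding genes were classed by their biotype there.

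Counts were analysed in R 4.3.3 with edgeR 4.0.16: filterByExpr on group (minimum count 10, minimum total 15), TMM scaling, robust dispersion and quasi-likelihood fits, and Benjamini-Hochberg adjustment with a threshold of 0.05. CPM values use TMM-scaled library sizes. log2 CPM uses a prior count of 2. Where a count is 0, the upper limit given is 3 counts of the library total, which covers counting error only. The SE of a log2 fold change is that of the difference of group means of log2 CPM over libraries, not a model output. The common biological coefficient of variation was 0.149. The labels give no batch, and no covariate entered the fit. No library columns were identical, and the highest Spearman correlation between libraries was 0.938.

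Gene lists were fixed before the data were examined: 37 lists with 842 symbols, of which 814 were found in the table. Each list was tested with camera from limma 3.58.1 on voom values with a preset correlation of 0.01, with an estimated correlation, and with fry, adjusted over the 37 lists. With an estimated correlation no list passed the threshold, against 13 with the preset one; slow fibre genes alone had an unadjusted p under 0.05 (0.0267). fry, which does not compare a list with other genes, is given where it passed the threshold and camera did not. A median per library is the median over list members of log2 CPM minus the control mean. The text names Kcnq1ot1 and Lncpint, 9 genes of muscle fibres and atrophy fixed beforehand, the 10 largest rises and 10 largest falls among called genes with a mean of at least 1 CPM, a symbol that is not provisional and at least 8 of 10 exposed libraries on the same side of the control mean, up to 4 members of each list by smallest p, and the 5 lncRNAs with the smallest adjusted p. A few of the genes this rule takes are not reported here.

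Library values were compared by 2-sided permutation tests with 100000 resamples (scipy), and exactly where a library was left out. lncRNAs and protein-coding genes were compared by a Mantel-Haenszel test in 10 strata of mean expression. Spread was the median over genes of the log2 ratio of variances. Groups were also compared with 100 splits of the 20 libraries drawn with a fixed seed, the real one included; an odds ratio was taken only from splits with at least 10 called genes.

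The tests were run on simulated data first, with 200 of 16778 genes changed in 10 against 10 libraries drawn from the real means and library sizes. The edgeR test recovered 53.7% of genes changed 1.25-fold, 76.1% of those changed 1.5-fold and 100% of those changed 3-fold, and 7 of 160 calls were false. The simulated changes were few and as often up as down. They do not test the scaling or the share of false calls in the real data, where 57.6% of tested genes were called.

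Alternatives fixed before the data were examined were DESeq2 size factors, upper-quartile factors, library size alone, the DESeq2 1.42.0 test, limma-voom with quality weights, no filter, a CPM of 1 in 10 libraries, leaving out mitochondrial and the 10 most abundant genes, the sample number as a block, a fold threshold of 1.2, an adjusted p under 0.01, each library left out, camera with an estimated correlation, fry, 20 strata, and the median absolute deviation for the spread. The comparison without exposed replicates 1 to 4, the direction of called genes by class, the tests on transcript models inside introns, and lists of perineurial and repair Schwann genes were chosen after seeing the data. For the explanation by a lower share of fibre RNA, the bound of 2 SD did not name the list it referred to; the SD of the Schwann medians, the stricter reading, was used, although a rise smaller than 2 SD cannot meet it, and a further test on endothelial and tendon markers was added afterwards.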

Results

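The series measured RNA in the soleus muscle of C57BL/6J mice, a hind-limb muscle rich in slow and oxidative fibres. One group of 10 mice was exposed to 14 days of hind-limb unloading together with ionizing radiation and a stress treatment given through the diet. The control group of 10 mice was sham-irradiated. The 3 exposures were applied together, so their separate effects cannot be told apart in this design, and the groups are called exposed and control here. Nothing in the labels says more about the origin of the replicates than a group size of 10 mice, and p-values measure the spread between these samples. Each of the 20 libraries was made from 90 ng of total RNA after removal of ribosomal RNA. The read counts summed to between 17336017 and 43424464 per library, and no difference in totals between the groups passed a permutation test (adjusted p = 0.628). Of 56941 gene rows, 16778 passed the count filter and were tested. All 20 libraries held counts of the Y-linked gene Kdm5d and at most 11 counts of Xist, the transcript of the inactive X chromosome.

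The exposed muscles differed from the controls across much of the transcriptome. Genes of slow fibres and of oxidative metabolism were lower, genes of the fastest fibres were higher, and the 2 lncRNAs named in the series title were both higher. In the edgeR quasi-likelihood test, 9663 genes (57.6% of those tested) changed at a Benjamini-Hochberg adjusted p under 0.05, of which 4813 were higher and 4850 lower in exposed muscles. Most of these changes were small, with a median absolute log2 fold change of 0.442, and 641 genes rose and 566 fell by at least 2-fold. The first principal component held 47.4% of the variance and separated all 10 exposed from all 10 control libraries. Named genes described as changed lay on the stated side of the control mean in all 10 exposed libraries unless a lower number is given. Scaling by library size alone gave 5946 higher and 3756 lower genes, so that the share of higher genes went from 49.8% to 61.3%. Exposed replicates 1 to 4 held far higher levels of nerve markers than the other libraries, and without them, a comparison chosen after seeing the data, 4310 genes were higher and 4466 lower. These 4 libraries also stood apart from exposed replicates 5 to 10 in other values. Their list medians were 0.15 to 0.37 against 0.54 to 0.89 log2 units for fast fibre genes. For glycolysis and glycogen genes they were -0.14 to 0.32 against 0.44 to 0.69. For oxidative phosphorylation genes they were -0.79 to -0.69 against -0.56 to -0.40. TMM factors were 1.05 to 1.16 against 0.946 to 1.01.

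The first question was whether Kcnq1ot1 and Lncpint, the lncRNAs of the series title, differed between the groups. Kcnq1ot1, a long antisense transcript that starts within Kcnq1 and silences neighbouring imprinted genes, rose from 168.1 ± 18.0 to 206 ± 18.3 CPM (normalised read counts, scaled to library size; SD, n = 10 each). This was a 1.23-fold rise (log2 fold change 0.29 ± 0.067 SE, edgeR adjusted p = 0.000276), and all 10 exposed libraries lay above the control mean. Lncpint, a lncRNA induced by p53, rose from 72.8 ± 16.4 to 128.9 ± 21.1 CPM, a 1.77-fold rise (log2 fold change 0.82 ± 0.131 SE, edgeR adjusted p = 1.08e-05). The lowest exposed library held 100.6 CPM of Lncpint and the highest control 96.8 CPM. The ranges of Kcnq1ot1 overlapped, with controls from 124.5 to 191.7 CPM and exposed libraries from 179.9 to 241.1 CPM. Against a fold of 1.2 the rise of Kcnq1ot1 did not pass the threshold (edgeR glmTreat adjusted p = 0.308). The strand setting of the counting is not given in the sources used here, so the value of Kcnq1ot1 is uncertain as far as reads of Kcnq1, on the opposite strand, were counted with it. Kcnq1 itself stood at 0.809 CPM in controls and 0.776 CPM in exposed libraries.

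**Figure D1:**
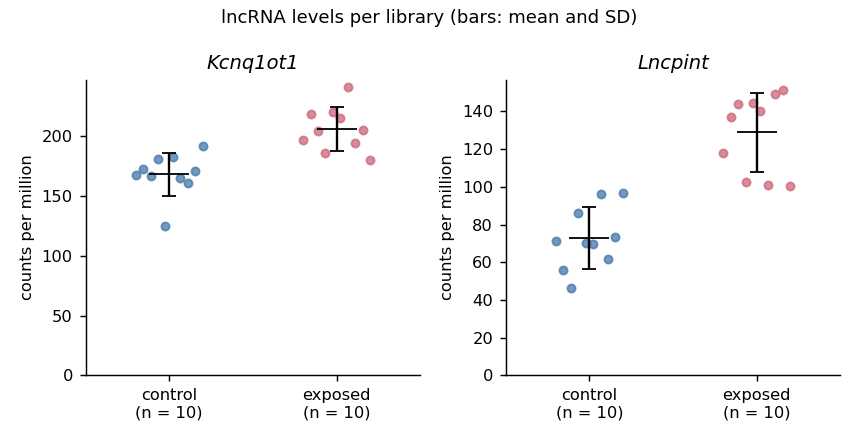
Normalised read counts (CPM) of Kcnq1ot1 and Lncpint (vertical axes) in 10 control and 10 exposed libraries; points are libraries, and black bars give the mean and SD. The group means are 168.1 and 206 CPM for Kcnq1ot1 and 72.8 and 128.9 CPM for Lncpint.

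Genes of slow fibres fell together. All 16 measured members of the slow fibre list were lowered, with a median 2.98-fold decrease, and each was past the threshold. The slow myosin heavy chain Myh7 fell from 10180 ± 1151 to 4650 ± 1858 CPM (SD, n = 10 each), a 2.19-fold decrease (edgeR adjusted p = 2.84e-05). Phospholamban, Pln, a regulator of the slow and cardiac calcium pump, was 4.41-fold lower, the slow light chain Myl3 fell from 2775 to 817 CPM, the calcium buffer Casq2 was 3.70-fold lower and Myoz2 was 3.71-fold lower. The list was lower than other genes by camera (adjusted p = 1.13e-08), a call that was lost at adjusted p = 0.628 with an estimated correlation.

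Fast fibre genes went mostly the other way, with an exception in Myh2. Of 17 measured members, 12 were raised and 2 lowered, and the counts were the same when adjusted over the list alone, as they were for slow fibre genes. Myh4, the heavy chain of the fastest fibres (type 2B), rose 20.9-fold, from 647 ± 495 to 13540 ± 2203 CPM (SD, n = 10 each; edgeR adjusted p = 1.08e-06). Myh1, the type 2X heavy chain, rose 4.19-fold to 15160 ± 2476 CPM (edgeR adjusted p = 2.67e-11). Myh2, the heavy chain of the oxidative type 2A fibres, fell 31.2-fold, from 10020 ± 798 to 320.9 ± 257 CPM (edgeR adjusted p = 9.53e-11). The DESeq2 test gave 14.0-fold, under a default setting that replaces outlying counts by a trimmed mean over all libraries. Exposed replicate 10 stood at 1035 CPM and the next highest exposed library at 334. Whether that count was replaced was not checked, so 14.0-fold is not taken as a second estimate of the fall. The fast calcium pump Atp2a1 was 2.44-fold higher and Myoz1 3.29-fold higher. The list was higher than other genes by camera (adjusted p = 0.00109, or adjusted p = 0.679 with an estimated correlation). Without exposed replicates 1 to 4, 13 members were raised and 2 lowered (camera adjusted p = 1.43e-05). Myosin heavy chain genes are similar in sequence, and how reads shared between them were counted is not given in the sources used here.

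**Figure D2:**
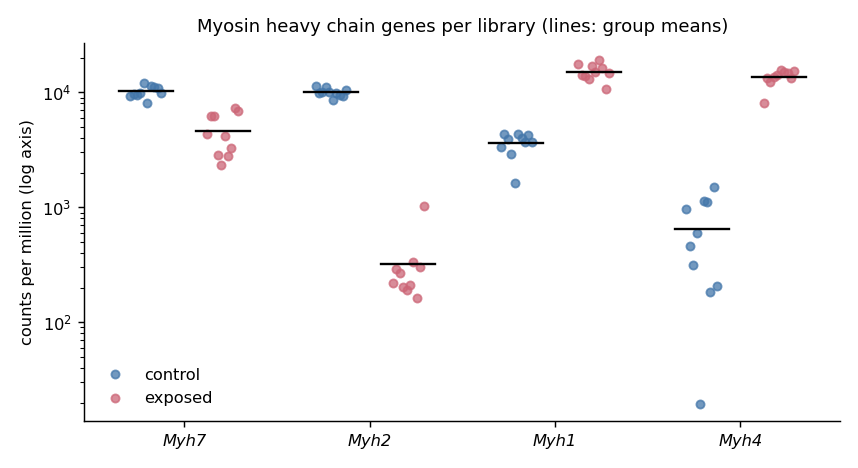
Normalised read counts (CPM) on a log axis for 4 myosin heavy chain genes in 10 control and 10 exposed libraries; points are libraries and lines are group means. Myh2 falls from a mean of 10020 to 320.9 CPM and Myh4 rises from 647 to 13540 CPM, with no overlap between the groups for any of the 4 genes.

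Among called genes with a mean of at least 1 CPM and a symbol that is not provisional, the largest rises after Myh4 were in the lncRNA Myhas (15.1-fold), Ccdc192 (13.2-fold), the fast-fibre actinin Actn3 (11.6-fold), the synaptic vesicle protein Sv2b (10.2-fold) and the secreted ligand Wnt4 (9.92-fold). Srrm4os, Odf3l2 and Gabrr2 followed, with rises of 8.45, 8.14 and 6.97-fold. Without control replicate 9, which held 2.94 CPM of Odf3l2, the rise of that gene was 23.4-fold, and with voom quality weights 18.1-fold. By the same limits, the largest falls after Myh2 were in Bdh1, an enzyme of ketone body metabolism (19.2-fold), and Lrrc52 (17.8-fold). Tmem171 fell 12.1-fold, the fatty acid carrier Fabp3 11.9-fold, the splicing regulator Srrm4 9.57-fold, the slow regulatory light chain Myl2 8.83-fold, Dusp18 8.61-fold and Tecta 7.91-fold. Fabp3-ps1, a pseudogene, was 13.9-fold lower, but it resembles Fabp3 in sequence and its value is uncertain. Values of the antisense lncRNAs Myhas and Srrm4os, and of Srrm4, are uncertain because the strand setting is not given. All of these changes passed the edgeR test, with adjusted p of 0.000755 or less.

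Genes that respond to glucocorticoids were mostly higher in the exposed muscles. Of 30 measured members, 18 were raised and 1 lowered, or 20 and 1 when adjusted over the list alone. Over all tested genes, 57.6% were called. The list median was not raised in every exposed library. It stood at -0.12 log2 units in exposed replicate 1 and 0.115 in exposed replicate 10, within the control range of -0.484 to 0.237. Fkbp5, a glucocorticoid-induced chaperone partner, rose from 48.3 ± 15.6 to 167.1 ± 38.2 CPM (SD, n = 10 each), a 3.47-fold rise (edgeR adjusted p = 4.58e-07). Glutamine synthetase, Glul, was 2.46-fold higher, Pik3r1, a regulatory subunit of phosphoinositide 3-kinase, 2.47-fold higher, and the cell cycle inhibitor Cdkn1a 3.87-fold higher. The lowered member was the glucocorticoid receptor gene Nr3c1, named after its value was seen. Camera placed the list above other genes (adjusted p = 0.00259; adjusted p = 0.679 with an estimated correlation).

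Members of the p53 and DNA damage list moved in both directions. Of 26 measured, 9 were raised and 6 lowered, over all genes and adjusted over the list alone, where 57.6% of all tested genes were called. Camera did not pass the threshold (adjusted p = 0.17, or 0.679 with an estimated correlation). By fry, which does not compare a list with other genes here or below, the list was higher on balance (adjusted p = 8.51e-06). Eda2r, a p53 target and a receptor of ectodysplasin, rose 3.99-fold, from 17.5 ± 2.19 to 69.8 ± 23.8 CPM (edgeR adjusted p = 4e-09). Gadd45a was 2.62-fold higher, the pro-apoptotic gene Bbc3 2.35-fold higher and Zmat3 1.52-fold lower. Cdkn1a, also in the glucocorticoid list, rose from 25.2 ± 4.90 to 97.1 ± 32.3 CPM. Without exposed replicates 1 to 4, chosen after seeing the data, 8 members were raised and 2 lowered.

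The atrophy list was mixed as well. Of 25 measured ubiquitin ligases and atrophy genes, 10 were raised and 6 lowered, over all genes and adjusted over the list alone (camera adjusted p = 0.393; fry adjusted p = 0.0305, higher). Fbxo32, the muscle ubiquitin ligase also called atrogin-1, rose 1.40-fold, from 543.3 ± 76.9 to 760.4 ± 204 CPM (edgeR adjusted p = 0.00734), in 8 of 10 exposed libraries. Trim63, the ligase MuRF1, stood at 174.9 ± 30.9 CPM in controls and 165.7 ± 37.3 CPM in exposed libraries and did not pass the test (edgeR adjusted p = 0.633). Mstn, which encodes the growth inhibitor myostatin, rose 3.08-fold from 1.43 ± 0.821 CPM (edgeR adjusted p = 1.85e-05). Fbxo31 was 1.82-fold higher, Foxo4 1.32-fold higher, the translation repressor Eif4ebp1 1.70-fold higher and the ubiquitin-conjugating enzyme Ube2b 1.26-fold lower. The rise of Fbxo32 did not pass the edgeR test without exposed replicates 1 to 4 (adjusted p = 0.0508), on fewer libraries and with a log2 fold change of 0.473 against 0.485 over all.

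Energy metabolism genes were lower on the oxidative side. Of 75 measured nuclear genes of oxidative phosphorylation, 73 were lowered and the other 2 did not pass the test, with a median 1.49-fold decrease; Uqcrq was 1.95-fold lower, Cox6b1 1.71-fold lower and Ndufb5 1.84-fold lower. Camera gave adjusted p = 2.13e-26 for this list (adjusted p = 0.628 with an estimated correlation). Without exposed replicates 1 to 4, 69 members were lowered, and the median log2 fold change was -0.459 against -0.578 over all. Of 28 genes of fatty acid uptake and oxidation, 26 were lowered and the other 2 did not pass the test, among them Fabp3, Acaa2 (2.22-fold) and lipoprotein lipase, Lpl (1.96-fold); camera gave adjusted p = 2.15e-12 (adjusted p = 0.628 with an estimated correlation). Of 12 mitochondrially encoded mRNAs, 5 were lowered and 7 did not pass the test, with mt-Co1 1.54-fold, mt-Cytb 1.27-fold and mt-Nd6 1.61-fold lower. That list missed the camera threshold (adjusted p = 0.109) and passed it without control replicate 9, which held little mitochondrial RNA (camera adjusted p = 0.0247), with library size alone (0.0389) and with no filter on low counts (0.00213), and it was lower by fry (adjusted p = 0.0284); 3 were lowered without exposed replicates 1 to 4. Of 22 genes of glycolysis and glycogen metabolism, 15 were raised and 6 lowered, with Gpd1 3.98-fold higher, Gpi1 1.55-fold higher and Ugp2, which makes the precursor of glycogen, 2.77-fold lower (camera adjusted p = 0.0139; adjusted p = 0.757 with an estimated correlation). Adjusted over the list alone, the counts of these 4 lists were the same. The median of the glycolysis and glycogen list lay below the control mean in exposed replicate 1 (-0.14 log2 units). Without exposed replicates 1 to 4, 16 genes of that list were raised and 5 lowered (camera adjusted p = 7.08e-05).

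Chaperones fell and ribosomal protein genes rose slightly. Of 20 heat shock proteins and chaperones, 15 were lowered and 5 did not pass the test, with Cryab 5.32-fold, Hspa1l 3.16-fold and Hsph1 2.14-fold lower (camera adjusted p = 2.36e-07; adjusted p = 0.628 with an estimated correlation). Of 76 ribosomal protein genes, 40 were raised and 5 lowered, or 42 and 5 when adjusted over the list alone, by a median of 1.08-fold (camera adjusted p = 0.000392; adjusted p = 0.759 with an estimated correlation). With upper-quartile scaling or library size alone, 56 ribosomal protein genes were raised and 2 lowered, and without exposed replicates 1 to 4, 41 and 2. Rpl10a and Rpl12 were 1.36-fold higher and Rps13 1.60-fold lower; these genes have many pseudogenes, and their values are uncertain. Of 36 proteasome subunits, 23 were lowered and 7 raised, with Psmd14 and Psma1 1.45-fold and Psmd10 1.68-fold lower (camera adjusted p = 0.00478; adjusted p = 0.757 with an estimated correlation). Without exposed replicates 1 to 4 the proteasome list missed the threshold (camera adjusted p = 0.0579). Of 30 autophagy and lysosome genes, 10 were raised and 13 lowered, a balance that became 11 and 9 with upper-quartile scaling and 11 and 8 with library size alone (camera adjusted p = 0.694). Tfeb, a master regulator of lysosome genes, was 1.53-fold higher, Wipi1 2.01-fold lower and the protease Ctsd 1.59-fold lower.

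Camera did not set the stress response lists apart from other genes. Of 18 genes of the unfolded protein and integrated stress response, 3 were raised and 8 lowered; the chaperones Hspa5 and Hsp90b1 were 2.21-fold and 1.46-fold lower, and the cystine transporter Slc7a11, at 0.196 CPM in controls, was 8.46-fold higher (camera adjusted p = 0.507). By fry, which asks whether a list moves on balance without comparing it with other genes, this list was lower (adjusted p = 0.000225) although its median change was 0, and with upper-quartile scaling or library size alone 5 of its genes were raised and 6 lowered. Without control replicate 5, 5 were raised. Of 25 antioxidant genes, 10 were raised and 9 lowered, or 11 and 9 when adjusted over the list alone, with Gstm1 2.35-fold higher and Prdx6 1.51-fold lower (camera adjusted p = 0.765). Of 27 interferon response genes, 1 was raised, H2-K1, and 3 were lowered, or 1 and 1 when adjusted over the list alone; with library size alone 4 were raised and 1 lowered (camera adjusted p = 0.93). With a library left out, 3 were raised without control replicates 1 or 2 or exposed replicate 9, 2 without exposed replicates 1, 6, 7 or 10, and 1 was lowered without control replicate 2. Without exposed replicates 1 to 4, 8 interferon response genes were lowered and H2-K1 did not pass the edgeR test (adjusted p = 0.136). Counts for the proteasome, chaperone, autophagy and unfolded protein lists were the same when adjusted over the list alone. Lists whose median, mean and camera direction differed in sign were the unfolded protein response (median 0, mean 0.24, down), antioxidant genes (median -0.03, mean 0.28, up), the Kcnq1 domain (median -0.12, mean 0.00, down), erythroid markers (median -0.23, mean 0.01, down) and smooth muscle markers (median -0.03, mean 0.03, up).

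Extracellular matrix genes were lower, with 26 of 35 measured members lowered and 3 raised, or 28 and 3 when adjusted over the list alone. Periostin, Postn, fell 6.18-fold, from 51.8 ± 13.1 to 8.37 ± 2.20 CPM, biglycan, Bgn, 2.53-fold and the crosslinking enzyme Loxl1 1.68-fold (camera adjusted p = 1.18e-06; adjusted p = 0.679 with an estimated correlation). All 9 tendon markers were lowered in the same libraries, as described with the cell type markers. Signalling lists were mixed. Of 25 genes of insulin, IGF and myostatin signalling, 12 were raised and 10 lowered, or 12 and 11 when adjusted over the list alone, with Igfbp5 3.11-fold, Smad3 2.42-fold and Rps6kb1 1.32-fold higher (camera adjusted p = 0.426). Of 20 genes of denervation and the neuromuscular junction, 9 were raised and 6 lowered, with the agrin receptor Lrp4 1.98-fold and Gadd45a 2.62-fold higher and Prkar1a 1.47-fold lower (camera adjusted p = 0.507); with library size alone 9 were raised and 3 lowered. Of 14 satellite cell and myogenic genes, 7 were raised and 2 lowered, or 8 and 2 when adjusted over the list alone; Myod1 was 2.74-fold and Spry1 1.37-fold higher, and the embryonic myosin Myh3 3.68-fold lower (camera adjusted p = 0.316). Of 14 cell cycle genes, 3 were raised and 6 lowered, with Rrm2 1.91-fold higher and Mcm6 and Kif11 1.65-fold and 2.80-fold lower (camera adjusted p = 0.58); 3 were lowered with a filter at a CPM of 1. Of 19 clock genes, 6 were raised and 2 lowered, with Rora 1.69-fold, Cry1 1.54-fold and Tef 1.35-fold higher (camera adjusted p = 0.17); 1 was lowered without exposed replicates 1 to 4. Counts for the denervation, cell cycle and clock lists were the same when adjusted over the list alone. By fry, insulin, IGF and myostatin signalling (adjusted p = 1.79e-05), clock (0.000429), satellite cell (0.00959) and denervation genes (0.0496) were higher on balance and cell cycle genes lower (0.00516).

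**Figure D3:**
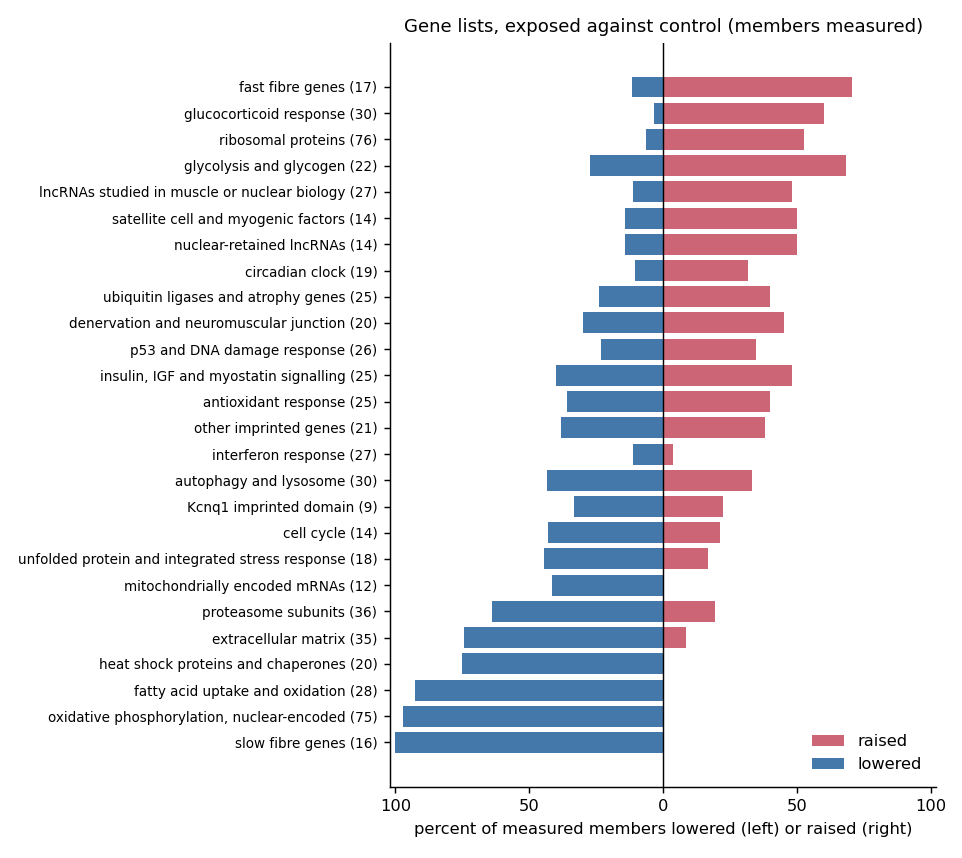
Percent of the measured members of each gene list that were raised (right) or lowered (left) in exposed against control libraries by the edgeR test; the number measured is in parentheses. Slow fibre genes (16 of 16) and oxidative phosphorylation genes (73 of 75) are lowered, and fast fibre genes (12 of 17) and glucocorticoid response genes (18 of 30) are raised.

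Beyond the title genes, lncRNAs changed in both directions. Of 27 lncRNAs known from muscle or nuclear biology, 13 were raised and 3 lowered, or 5 lowered without exposed replicates 8 or 10. H19, an abundant imprinted lncRNA, fell 3.98-fold, from 1366 ± 115 to 343.2 ± 96.1 CPM (edgeR adjusted p = 1.27e-11), Peg13 rose 1.69-fold and Jpx 1.70-fold. This list missed the camera threshold (adjusted p = 0.0522) and passed it when any of control replicates 4, 6 and 9 or exposed replicates 1, 2, 3 and 4 was left out (camera adjusted p from 0.0338 to 0.0488). It also passed with no filter on low counts (0.017), with voom quality weights (0.0436) and without exposed replicates 1 to 4 together (camera adjusted p = 0.0182). By fry, this list (adjusted p = 1.79e-05) and the nuclear-retained lncRNAs (3.49e-05) were higher on balance and the other imprinted genes lower (0.00394). Of 14 nuclear-retained lncRNAs, 7 were raised and 2 lowered, with Ftx 1.45-fold and Airn 1.36-fold higher (camera adjusted p = 0.17; adjusted p = 0.0374 with no filter on low counts). Of 9 measured genes of the Kcnq1 imprinted domain, 2 were raised, Kcnq1ot1 and the cell cycle inhibitor Cdkn1c (2.15-fold), and 3 lowered, among them Cd81 (1.23-fold); with library size alone 2 were raised and 1 lowered (camera adjusted p = 0.793). Of 21 other imprinted genes, 8 were raised and 8 lowered, among the latter Snrpn, at 1.76-fold lower (camera adjusted p = 0.765); 5 were raised and 6 lowered without exposed replicates 1 to 4. Counts for these 4 lists were the same when adjusted over the list alone. The 5 lncRNAs with the smallest edgeR adjusted p were 4931413K12Rik (10.6-fold higher), AC122117.2 (8.77-fold higher), A730036I17Rik (29.6-fold lower), 5430401H09Rik (53.5-fold lower) and Gm49490 (11.3-fold lower).

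lncRNAs and protein-coding genes were compared as classes. Of 1326 tested lncRNAs, 512 were raised and 217 lowered, and of 13084 protein-coding genes 3367 were raised and 4443 lowered. At a like level of expression, in 10 strata, lncRNAs were called more often than protein-coding genes (Mantel-Haenszel odds ratio 1.58, 95% confidence interval 1.39 to 1.79, p = 2.28e-12). Over all levels, however, 55% of lncRNAs and 59.7% of protein-coding genes were called. This p-value and interval are across genes, which are not independent replicates, and do not measure the spread between mice. Splits of the libraries that mixed the groups gave odds ratios up to 1.8. The lncRNA class includes some transcript models inside introns, and without these models 422 lncRNAs were raised and 210 lowered.

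Markers of other cell types also differed between the groups. Schwann cell and nerve markers were higher, with 13 of 14 raised, or 14 when adjusted over the list alone, among them Cdh19 (2.80-fold, or 1.56-fold without exposed replicates 1 to 4). The rise was uneven: the median of the list stood 3.59 to 8.74-fold above the control mean in exposed replicates 1 to 4, and 5 of the 10 exposed libraries lay within the control range. Camera gave adjusted p = 0.0202 (adjusted p = 0.773 with an estimated correlation), adjusted p = 0.0643 with upper-quartile scaling, 0.0899 with library size alone, 0.0541 with a filter at a CPM of 1 and, without exposed replicates 1 to 4, adjusted p = 0.201 with 5 markers raised and 2 lowered. Tendon markers were lower, with 9 of 9 lowered over all genes and adjusted over the list alone, such as Scx (3.18-fold) and Kera (6.15-fold; camera adjusted p = 0.000961; adjusted p = 0.679 with an estimated correlation). Of 16 endothelial markers, 7 were lowered, led by Eng (1.85-fold) and Sox17 (1.63-fold), and 1 raised, or 3 with upper-quartile scaling or library size alone; camera was near its threshold (adjusted p = 0.0498; adjusted p = 0.757 with an estimated correlation) and missed it without any of control replicates 1, 2, 3 and 10 or exposed replicates 6, 8, 9 and 10 (0.054 to 0.0739), with upper-quartile scaling (0.0643), library size alone (0.0899), a filter at a CPM of 1 (0.11) or the DESeq2 test (0.0896).

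The remaining marker lists did not pass the camera threshold at the settings used here, and macrophage markers passed it with no filter on low counts (adjusted p = 0.0321). Of 18 macrophage markers, 5 were raised and 13 did not pass the test, led by Cd163 (1.72-fold) and F13a1 (1.38-fold), or 3 when adjusted over the list alone (camera adjusted p = 0.112); with upper-quartile scaling, library size alone or the DESeq2 test, or without control replicate 6, 8 were raised, and without exposed replicates 1 to 4, 3. F13a1 did not pass the edgeR test without exposed replicates 1 to 4 (adjusted p = 0.0516). Among 13 markers of fibro-adipogenic progenitors, 3 were raised and 4 lowered, with Ly6a 1.47-fold and Lum 1.67-fold lower (camera adjusted p = 0.694); with library size alone 3 were raised and 2 lowered, and without exposed replicates 1 to 4, 3 and 7. Among 12 smooth muscle and pericyte markers, 3 were raised, led by Lmod1 (2.13-fold), and 2 lowered, led by Cspg4 (1.52-fold; camera adjusted p = 0.793), against 4 and 1 with upper-quartile scaling or library size alone and 3 and 1 without exposed replicates 1 to 4. Of 13 adipocyte markers, Car3, which muscle also expresses, was 2.04-fold lower and Retn 2.57-fold higher, in 8 of 10 libraries (camera adjusted p = 0.765); Retn did not pass the edgeR test without exposed replicate 4 (adjusted p = 0.0701), nor without exposed replicates 1 to 4 (1.42-fold, adjusted p = 0.421) or with voom quality weights (adjusted p = 0.0938). No adipocyte marker was raised when adjusted over the list alone or without exposed replicate 4, and 3 were raised with each other scaling and without any of control replicates 1 and 2 or exposed replicates 8, 9 and 10, and 2 without exposed replicate 6. Without exposed replicates 1 to 4 the adipocyte list turned, with 0 raised and 3 lowered and a median of -0.257 log2 units against 0.66 over all, and so did the median of erythroid markers, 0.097 against -0.225. Few markers of blood cells were measured: Csf3r was raised (in 9 of 10 libraries) of 2 neutrophil markers, or both when adjusted over the list alone, Ighm (in 8) of 2 lymphocyte markers and Slc4a1 of 6 erythroid markers, with camera adjusted p = 0.467, 0.467 and 0.793. By fry the neutrophil (adjusted p = 0.0102) and lymphocyte markers (0.0127) were higher, and the count of raised neutrophil markers went from 0 with a filter at a CPM of 1 to 5 with no filter; it was 2 or 3 without any of control replicates 1, 4, 6 and 9 or exposed replicates 2, 3, 4, 5 and 9. In the sex check, Kdm5d and Ddx3y differed by 1.09-fold up and 1.10-fold down, each in 8 of 10 libraries (camera adjusted p = 0.93); the edgeR call of Kdm5d was lost with no filter on low counts (adjusted p = 0.0579), and that of Ddx3y with each other scaling (0.0517 to 0.33) and without control replicate 5 or exposed replicates 2, 3 or 9 (0.0507 to 0.066). Counts for these lists not given separately were the same when adjusted over the list alone.

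**Figure D4:**
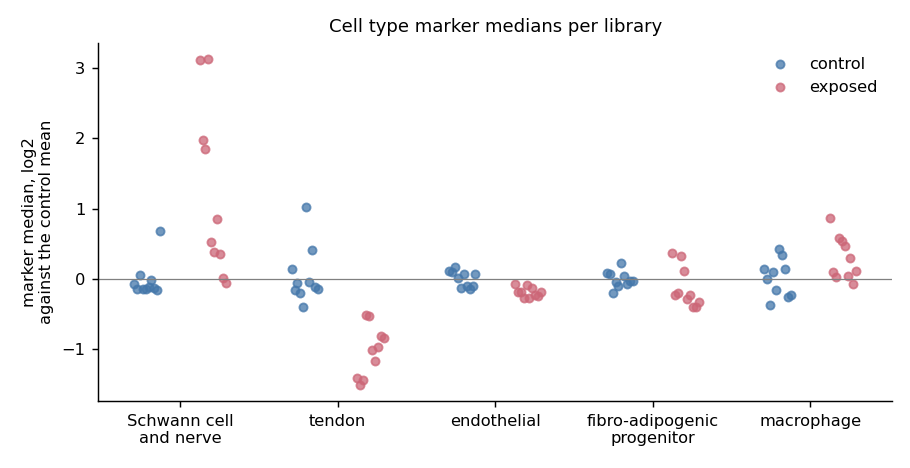
Median log2 level of each cell type marker list against the control mean (vertical axis) in 10 control and 10 exposed libraries; points are libraries. Schwann cell and nerve markers reach 3.13 in exposed libraries and 0.682 in controls, and tendon markers lie between -1.51 and -0.503 in exposed libraries.

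Composition of the libraries was compared by 2-sided permutation tests of 15 values, with Benjamini-Hochberg adjustment. Mitochondrially encoded genes took 8.5 ± 1.04% of counts in controls and 6.71 ± 0.932% in exposed libraries (SD, n = 10 each; permutation adjusted p = 0.0055), lower in all 10. The 10 most abundant genes took 32.0 ± 0.702% and 33.4 ± 1.18% (permutation adjusted p = 0.00981), higher in 8, and titin, Ttn, alone took between 17.6 and 21.7%. Library size (adjusted p = 0.628), genes detected (24688 ± 972 and 25086 ± 635; adjusted p = 0.367) and the share of haemoglobin counts (adjusted p = 0.383) did not pass the threshold of the permutation test. Among marker medians, the difference in log2 units was 1.23 for Schwann cells (permutation adjusted p = 0.0072, in 9 of 10 exposed libraries), -1.06 for tendon (0.0003, in 10), -0.192 for endothelium (0.00465, in 10), 0.859 for neutrophils (0.00981, in 9) and 0.373 for lymphocytes (0.00981, in 9). The unadjusted p for tendon, 2e-05, is the smallest these resamples can give. The neutrophil and lymphocyte medians each rest on 2 measured markers, of 12 and 17 listed. Of each pair, 1 was called by edgeR over all genes. The differences for macrophage (0.278 in log2 units, permutation adjusted p = 0.0835), erythroid (adjusted p = 0.367), adipocyte (0.367), fibro-adipogenic (0.367) and smooth muscle markers (0.698) did not pass the threshold.

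Spread within groups was wider in exposed muscles by a median log2 variance ratio of 0.325. It was 0.136 by the median absolute deviation, and without exposed replicates 1 to 4, chosen after seeing the data, it was -0.008.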

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

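The tests of a lower fibre share and of all 3 explanations for the myosin genes were chosen after the results were seen; those of nerve tissue and of a Schwann injury response used lists added after the nerve markers were seen, with their bounds written before their own results. In 332 groups of 10 values, 37 values lay far from the rest, as measured by the gap to the nearest library over the range (on the log2 scale for genes), where chance gives about 1 in 20 groups. The nearest library of the same group is given in brackets.

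In control replicate 5, some genes of fast fibres were low: Myh4 stood at 19.5 CPM (182), Myh1 at 1632 (2923), Actn3 at 27.1 (138) and Myoz1 at 199 (246). The median of the fast fibre list, -0.26, was not far from the rest by this measure. Myh2, also in that list, stood at 10100 CPM, within the range of the other controls. The same library held 124 CPM of Kcnq1ot1 (161), 12.6 of Eda2r (16.7), 99.6 of Prdx6 (88.1) and 115 of Ddx3y (104), and a median of -0.14 for lncRNAs of muscle or nuclear biology (-0.0515).

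Control replicate 9, the shallowest library, held 5.88% of counts on mitochondrial genes (8), a median of -0.953 for mitochondrial mRNAs (-0.167), 5520 CPM of mt-Cytb (7353) and 380 of mt-Nd6 (699). It also held 2.94 CPM of Odf3l2 (0.268), 48.3 of Rps6kb1 (42.9), and 0 of Srrm4os (0.0937) and Slc4a1 (0.281), where a count of 0 allows up to 0.173 CPM by counting error. Ccdc192 stood at 0 CPM in control replicate 4 (0.12), where 0 allows up to 0.142 CPM. For Srrm4os and Ccdc192 this limit lies above the nearest library, so their gaps may come from counting error alone.

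Among other controls, Psma1 was 36.1 CPM in replicate 1 (41), Rpl10a 35 (41) and Cd163 4.13 (7) in replicate 3, and the extracellular matrix median 0.445 in replicate 6 (0.0948). Exposed replicate 1 held 8006 CPM of Myh4 (12330), 7.52 of Myhas (12.6), 11.1 of Dusp18 (17.5), 44.5 of Tfeb (56.5) and 13.9 of Cdkn1c (17.3). Exposed replicate 2 held 0.036 CPM of Srrm4 (0.153) and a Kcnq1 domain median of -0.282 (-0.142). Exposed replicate 3 held 120 CPM of mt-Nd6 (364) and a mitochondrial mRNA median of -1.58 (-0.793). Car3 was 743 CPM in exposed replicate 5 (1028), Psmd10 4.03 in replicate 6 (3.2), and in replicate 7 Myod1 was 47 (21.5) and the lncRNA list median 0.451 (0.226).

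Nerve markers stood apart in control replicate 10, with a Schwann median of 0.682 (0.0576), and more so in exposed replicates 1 to 4. A lower share of fibre RNA would raise all other cell types alike. Neutrophil (0.86) and lymphocyte medians (0.373) were higher in exposed libraries, but each rests on 2 measured genes. Adipocyte (0.61) and macrophage medians (0.295) lay above 0, but these differences did not pass the permutation test (adjusted p = 0.367 and 0.0835). Endothelial markers stood at a median of -0.184 (SD 0.071) in exposed libraries and tendon markers at -1.016 (SD 0.362). These falls argue against a lower fibre share as the whole cause. Among the endothelial, tendon, pericyte and fibro-adipogenic lists chosen for this test the largest rise was 0.016. That was below the Schwann rise of 1.213 by 1.197 (SE 0.377), although the bound written first, on the SD of 1.217, was too wide to be met. A Schwann injury response is argued against in exposed replicates 1 to 4 by the 3 measured repair genes of 7. Their median differed from that of the Schwann list by -1.014 (SE 0.361) over all exposed libraries. The difference lay between -2.73 and -1.756 in replicates 1 to 4 and between -0.865 and 0.27 in replicates 5 to 10. The 3 of 10 exposed libraries that went the other way were among the latter, where the test decides nothing. More nerve tissue in some samples may account for the rise: medians of 8 perineurial genes and of Schwann genes went together over the 10 exposed libraries (Pearson r = 0.759, permutation p = 0.012; Spearman rho = 0.661, permutation p = 0.043), but the libraries fall apart in 2 clusters, r was 0.315 (permutation p = 0.45) without the 2 farthest, and within replicates 5 to 10 it was 0.719 (exact permutation p = 0.108, n = 6), so the relation rests on few libraries and is not settled. A change of Schwann cells by the exposure remains open and untested.

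Myh2 stood at 1035 CPM in exposed replicate 10 (334), still far under the controls. A fast muscle taken along with part of the soleus is argued against because Myh2 kept 3.2% of its control mean while the median slow gene kept 33.7% (range 11.3 to 75.2%), which holds unless the added muscle itself expressed slow genes. Reads moved from one myosin gene to another would leave their sum as it was, if each shared read was counted once. The sum over 10 measured myosin heavy chain genes rose by 0.452 log2 units (SE 0.043). It was 29790 CPM or more in each exposed library and 26500 or less in each control, so such moves alone do not give these values. How shared reads were counted is not given, and reads left out or counted more than once could change the sum. Reads shared between myosin genes therefore stay open as a cause. Another muscle in place of the soleus cannot be told apart, since no profile of another muscle is among these libraries and Myh7 at 45.7% of its control mean decides nothing. A shift of fibre type by the combined exposure also remains open.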

How the results depend on the processing

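Kcnq1ot1 and Lncpint kept their direction in every alternative, Lncpint past the threshold in all and Kcnq1ot1 in all but a test against a fold of 1.2, where its log2 fold change of 0.293 had adjusted p = 0.308. That test, which asks for a larger change by construction, called 4864 genes, 2380 higher and 2484 lower; in it 6 atrophy genes were raised and 1 lowered, 11 glucocorticoid genes raised and 0 lowered, 2 p53 genes lowered and 1 fast fibre gene lowered. With an estimated correlation the adjusted p was 0.679 for glucocorticoid, 0.628 for slow fibre and 0.679 for fast fibre genes. By fry, which asks whether a list moves on balance and not against other genes, it was 0.0305 for atrophy and 8.51e-06 for p53 genes. With each library left out in turn, lowered glucocorticoid genes ranged from 1 to 2 and lowered fast fibre genes from 2 to 4, the highest without exposed replicate 7; the macrophage median difference ranged from 0.214 to 0.324 and passed the threshold without control replicates 6 or 7 or exposed replicate 9. Genes changed ranged from 9398 to 9643 over these. Without exposed replicates 1 to 4, chosen after seeing the data, 2 p53 genes were lowered, and the spread ratio reversed to -0.008; by the median absolute deviation it was 0.136. The cause was not tested for these. The sample number as a replicate block gave 9470 genes, 4654 higher and 4816 lower, 9230 of them called without it. With this block the edgeR calls of Fbxo32 (adjusted p = 0.0652), Kdm5d (0.0557) and Retn (0.0508) were lost. The list of lncRNAs of muscle or nuclear biology passed camera with it (adjusted p = 0.0483). No number correlated best with its own pair (correlations of deviations from -0.132 to 0.098, 0 of 10 above 0.1), so the numbers do not pair the mice. Other results (named genes and other lists) gave 6651 values with the same call or a count within 1.5 times, 36 newly past the threshold, 60 no longer past it and 123 counts that moved by over 1.5 times. No value past the threshold turned direction. Of lists short of it, adipocyte and erythroid markers turned by median and by camera direction without exposed replicates 1 to 4. Antioxidant genes turned there by median alone (0.105 against -0.033 log2 units over all). The difference of smooth muscle marker medians, 0.0186 over all, was -0.00219 without control replicate 8. Of the smallest simulated changes 53.7% were recovered at these library sizes; depth was not varied, so its part in this was not told from that of the spread between libraries.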

Other observations

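The tests of direction by class, of intronic transcript models and of Kcnq1 reads were chosen after the counts of changed lncRNAs were seen; for the intronic models the bounds were written before their own results, and the scalings and splits were planned.

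Transcript models that lie inside the introns of protein-coding genes were higher in exposed muscles. These were genes of the biotypes TEC and sense intronic, on the strand of the host gene and off protein-coding exons. Of 1037 such models tested, 514 were raised and 40 lowered by edgeR, with a median log2 fold change of 0.354, while their host genes had a median of 0.033. The median difference between model and host was higher by 0.302 in exposed libraries, with all 10 exposed libraries above every control (permutation p = 4e-05). Among called lncRNAs other than these models, 422 were raised and 210 lowered, an odds ratio of a rise of 2.65 against protein-coding genes (Fisher's exact test, 95% confidence interval 2.23 to 3.16, p = 1.58e-30, across genes, which are not independent replicates). Called intronic models shared that direction, with an odds ratio of 17 (95% confidence interval 12.2 to 24.1). Among called genes, 70.2% of all lncRNAs were raised, 72.5% of pseudogenes, 70.1% of rows matched to no class and 90.6% of other biotypes. Of called protein-coding genes it was 43.1%. Intronic models are counted within the lncRNAs and the other biotypes here, so the 90.6% is not separate from the result on these models. By pseudogenes and rows matched to no class, the direction was thus not particular to lncRNAs. It was not compared at a like level of expression.

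Kcnq1ot1 and Lncpint rose in the same libraries. Kcnq1 had a log2 fold change of -0.06, lower than Kcnq1ot1 by 0.349 (SE 0.117). Reads of Kcnq1 counted for Kcnq1ot1 would come from introns of Kcnq1, which its own count may not measure. That explanation therefore stays open while the strand setting is unknown. Under 3 other scalings the smallest log2 fold change of Kcnq1ot1 was 0.304. Each of these scalings moved the median gene up against TMM (by 0.01, 0.06 and 0.081 log2 units). They could therefore not have lowered the rise, and a scaling that moves values down was not tried. A general rise of intronic or nuclear RNA may account for Kcnq1ot1, which lay at percentile 43 of intronic models, so its rise was no larger than theirs. For Lncpint, at percentile 89, a general rise and a specific one cannot be told apart, since it lay between the bounds set beforehand. Regulation of either lncRNA by the exposure remains open.

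Chance was tested with 100 splits of the 20 libraries into 10 and 10. For genes changed, a chance division of the libraries is argued against: 1 of 100 splits, the real one, gave as many as 9663, and the highest other split gave 2868. The same held for genes higher (1 of 100 splits, 4813) and lower (1 of 100 splits, 4850), with 1661 the highest other in either direction. Only 4 splits, the real one included, called any gene. The others among them mixed the groups 8 to 2, which points to the structure of the groups themselves. The splits cannot tell the exposure from another difference between the groups, and the library codes run in order of group. For gene lists past the camera threshold, chance cannot be excluded: 17 of 100 splits gave at least 13 lists, and the highest other gave 17. For the spread within groups it cannot be excluded either, since 6 of 100 splits of group-centred values gave a ratio as far from 0 as 0.325, with 0.429 the highest other. For lncRNA against protein-coding calls, 4 splits called enough genes to give an odds ratio, too few for a share under 0.05, so the bound of 5 in 100 written beforehand had no meaning; all 4 were at least as far from 1 as 1.58, and the highest other was 1.8.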
